A study of Homo sapiens with 12 samples.

How the data were processed

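RNA was sequenced from cytotoxic CD8 T lymphocytes of 3 human donors, which had been expanded with Dynabeads, magnetic beads that carry activating antibodies. Per the labels, the cells were then stimulated for 4 h with OKT3, an antibody against the CD3 part of the T cell receptor, either alone or together with an antibody against DNAM1 (the product of CD226), NKG2D (the product of KLRK1) or CD28. The 12 libraries form 4 groups of 3, called OKT3, DNAM1, NKG2D and CD28 after what was added, and each library of a group carries the letter A, B or C in its title. The labels do not say that a letter stands for a donor. If libraries of a group did not come from separate donors, the p-values would measure only the spread between these libraries.

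The deposited values are raw counts, whole numbers of reads per gene with no normalization, in 2 tables that hold the OKT3 and DNAM1 libraries and the NKG2D and CD28 libraries. Per the submitters' processing notes, the tools were FastQC 0.11.8, STAR 2.7.9a, featureCounts, Subread 2.0.1 and DESeq2, and the genome build was GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand, reads of a gene and of a gene overlapping it cannot be told apart, which concerns KLRK1, whose locus also holds KLRK1-AS1 and KLRC4-KLRK1. Counts of near-identical copies, such as XCL1 and XCL2 or the histone genes, depend on how shared reads were counted and are uncertain as well. Per the labels, the OKT3 and DNAM1 libraries were made from rRNA-depleted total RNA and the NKG2D and CD28 libraries with a polyA-selecting kit, so that 4 planned comparisons comprise 2 within a kit and 2 across the 2 kits.

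The tables hold 60649 genes by Ensembl identifier. For 25379 of them no symbol is given, and 25276 of these were named through their identifier. Genes with no symbol took 1.01% to 1.33% of the counts of a library and stayed in the tests, since each names a gene by its identifier. GENCODE 29 on GRCh38 held 58337 of the identifiers and gave positions, exon lengths and GC content. All columns were used (0 left out). Library totals ran from 37377574 to 47268532 counts. A count of 3, taken as the floor of detection, corresponds to 0.0635 to 0.0803 CPM (counts scaled to the library total) at these depths, and such floors cover counting error only.

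Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after TMM normalization and the default expression filter, on the 6 libraries of the 2 groups compared. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and "edgeR adjusted p" below means this value. The design written before the data were examined had no block for the letter, with the block as its alternative. Fold changes are log2 values of the first group over the second with their standard error (SE), from the edgeR fit at its default prior count. The SE is the absolute fold change over the square root of the F statistic, which borrows spread from other genes. It does not measure the spread over the 3 letters. For IFNG with DNAM1 over OKT3 the differences within a letter were 1.00 in A, 0.86 in B and 2.25 in C. A prior count of 2 entered only the log2 CPM behind the differences within a letter and the length and GC corrections. CPM values are means ± SD over the 3 libraries of a group, scaled to the library total. Correlations between libraries and principal components used log2 CPM with TMM-scaled library sizes.

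Whether letters pair the libraries was decided before calls were compared. Over 12412 genes of at least 1 CPM on average, deviations from the group means correlated at 0.758 to 0.905 (median 0.843) in the 18 pairs of libraries that share a letter, and at -0.638 to -0.184 in the 36 pairs that differ in letter and group. Every pair sharing a letter lay above 0.1, so the letters pair the libraries, in a pairing that comes from the titles and the data. No 2 libraries were duplicates: a chi-square per gene between libraries, over genes with at least 20 counts, was 9.19 to 105 for a shared letter and 73.7 to 138 within a group.

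The procedure was tested on simulated data, with counts drawn from the real means of each letter and the real library sizes. Their spread was that of the fit with the block, and 200 well-counted genes were changed by 1.5-fold or 2-fold. Because this builds in the letter effects, a fit without the block was bound to do worse there. Without the block, edgeR recovered 0% of the changed genes at both sizes in each of the 4 planned comparisons. DESeq2 without the block recovered 14% to 23% of the 1.5-fold and 58% to 65% of the 2-fold changes with 0 false calls, and limma-voom 0%. With the block, edgeR recovered 81% and 95% for DNAM1 over OKT3 (23 false calls, 15460 genes), 76% and 92% for CD28 over NKG2D (10 false calls, 15532 genes), 81% and 96% for NKG2D over OKT3 (8 false calls, 15519 genes) and 83% and 94% for CD28 over OKT3 (8 false calls, 15430 genes). Each size was given to 100 genes, so for DNAM1 over OKT3 the 23 false calls stood beside 81 and 95 true ones. That is a larger false share than the threshold for calls is meant to allow. The calls of edgeR for DNAM1 over OKT3 may thus hold more false ones than the threshold implies. With the block DESeq2 recovered 69% to 79% and 89% to 92%. It made 8 false calls for DNAM1 over OKT3, where limma-voom with the block made 22, and 1 to 9 in the other comparisons. In the simulated data edgeR, the test of the design, recovered changes only with the block, which by construction cannot choose between the fits. Because the letters pair the libraries, fold changes, their SE and "rose" or "fell" come from the fit with the block unless stated otherwise.

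A set of 30 gene lists was fixed before the data were examined: early response, cytokines and chemokines, cytotoxic effectors, costimulatory receptors and activation markers, inhibitory receptors and exhaustion, NK receptors and adaptors, NF-kB targets, calcium and NFAT targets, IL-2 and STAT5 targets, glycolysis, amino acid transport and one-carbon metabolism, ribosome biogenesis, cholesterol synthesis, cell cycle, naive, memory and quiescence genes, interferon-stimulated genes, the integrated stress response, heat shock, PI3K-AKT-FOXO targets, CD8 T cell identity, markers of B cells, monocytes and dendritic cells, CD4 and regulatory T cells, NK cells, gamma delta T cells, and red cells and platelets, and, for RNA quality and kits, replication-dependent histones, small non-coding RNA genes, nuclear retained RNA and mitochondrially encoded genes. A gene can stand in several lists. Lists with at least 3 tested genes were tested two-sided with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation and with fry. The form with an estimated correlation also has few degrees of freedom, those left over in a fit of 6 libraries. A call lost there does not show that correlation between genes undid it. Calcium and NFAT targets of CD28 over NKG2D had an estimated correlation of -0.025, yet their camera adjusted p went from 6.04e-38 to 0.121. For DNAM1 over OKT3 with the block the estimates ran from -0.246 to 0.955 over the lists. They were 0.836 for early response, 0.546 for ribosome biogenesis, 0.416 for NF-kB targets and 0.338 for cytokines and chemokines. Where the correlation is far above the preset 0.01, the camera p at the preset is too small.

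Genes named in the text follow a rule fixed with the design. For DNAM1 over OKT3 and CD28 over NKG2D it takes the 10 called genes per direction with the largest change, at least 1 CPM on average and the same sign in all 3 letters, up to 4 members of each list with the smallest p, and always CD226, KLRK1, CD28, IFNG, TNF, IL2, GZMB and TNFRSF9. Where the fit without the block gave fewer than 10, the rest came from the fit with the block, which here supplied all of them. For other comparisons it takes those 8 genes and up to 10 called members of the cytokine, costimulatory and early response lists. Sex-linked genes used for sample identity, antigen receptor segments, HLA and KIR genes and features with no symbol were left out of the first part.

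Alternatives were DESeq2 1.42.0, limma-voom, median-ratio (RLE) size factors, no expression filter beyond a total count of at least 1, all 12 libraries in 1 fit, leaving out each library or letter, and an absolute log2 fold change of at least 1. Chosen after seeing the data were the comparisons of DNAM1 with CD28 and with NKG2D, list tests outside the 2 comparisons within a kit, and, with the block, fits with RLE, with no normalization factors, with no filter, with limma-voom, with all 12 libraries, with an absolute log2 fold change of at least 1, with a loess correction (span 0.5) for exon length or GC content, and with all libraries thinned to 37377574 counts. List tests that join the block with an estimated correlation or with fry were also chosen then. Correlations of fold changes between comparisons were computed only where no library was shared.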

Results

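The data were read counts of 12 libraries of human cytotoxic CD8 T cells, 3 for each of 4 stimuli given for 4 h: OKT3 alone, which engages the T cell receptor complex, and OKT3 with an antibody against DNAM1, NKG2D or CD28. DNAM1 and NKG2D are activating receptors found on natural killer (NK) cells and T cells, and CD28 is the classical costimulatory receptor of T cells. Library totals averaged 42227386 ± 648302 counts with OKT3, 45291072 ± 1425404 with DNAM1, 43043828 ± 5100619 with NKG2D and 43712023 ± 3004591 with CD28 (SD, n = 3 each). The 20 most abundant genes of a library took 8.58% to 11% of its counts. CD8A, which encodes a chain of the CD8 coreceptor, was abundant in every group, at 1890.3 ± 119 CPM with OKT3, 1728 ± 74.7 with DNAM1, 1851 ± 124 with NKG2D and 1886 ± 176 with CD28. Most B cell, monocyte and red cell markers were near the floor of detection, with list medians of at most 0.0507 CPM in any group. Other cell type lists were not: CD4 and regulatory T cell markers had medians of 27.2 to 31.3 CPM, with 11 of 13 genes over 1 CPM. NK cell markers had 8 of 14 genes over 1 CPM, and gamma delta T cell markers had medians of 3.34 to 5.74 CPM. The values thus do not show that such cells were absent.

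The receptors under study were all detected in cells given OKT3 alone. CD226 (ENSG00000150637.9, GRCh38 chromosome 18, 69831158 to 69961803) averaged 118 ± 7.78 CPM, CD28 (ENSG00000178562.18, chromosome 2, 203706475 to 203738912) 245 ± 47.4 CPM and KLRK1 (ENSG00000213809.9, chromosome 12, 10372353 to 10391874) 6.96 ± 2.7 CPM. The low KLRK1 value is uncertain, because the overlapping KLRK1-AS1 held 17.7 CPM and KLRC4-KLRK1 1.42 CPM on average over the 12 libraries. The effector genes followed throughout were IFNG (ENSG00000111537.5, chromosome 12, 68154768 to 68159747), TNF (ENSG00000232810.4, chromosome 6, 31575567 to 31578336), IL2 (ENSG00000109471.5, chromosome 4, 122451470 to 122456725), GZMB (ENSG00000100453.13, chromosome 14, 24630954 to 24634267) and TNFRSF9 (ENSG00000049249.9, chromosome 1, 7915894 to 7943165), all protein-coding.

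The letter in a library's title accounted for more of the variation than its stimulus. The first 2 principal components, with 47.3% and 29.3% of the variance, separated the letters A, B and C. The next component, with 11.4%, set the 3 DNAM1 libraries (-26.4, -7.88 and -28.7) apart from the other 9 (-2.31 to 15.5). Libraries sharing a letter correlated at 0.983 to 0.996 in log2 CPM across genes, and libraries of a group at 0.958 to 0.979, where genes are not independent replicates. The letter is a block in the fits whose values follow, because libraries that share it deviated together from their group means. The fit fixed beforehand, without the block, called 0 genes by edgeR in each of the 4 planned comparisons.

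**Figure D1:**
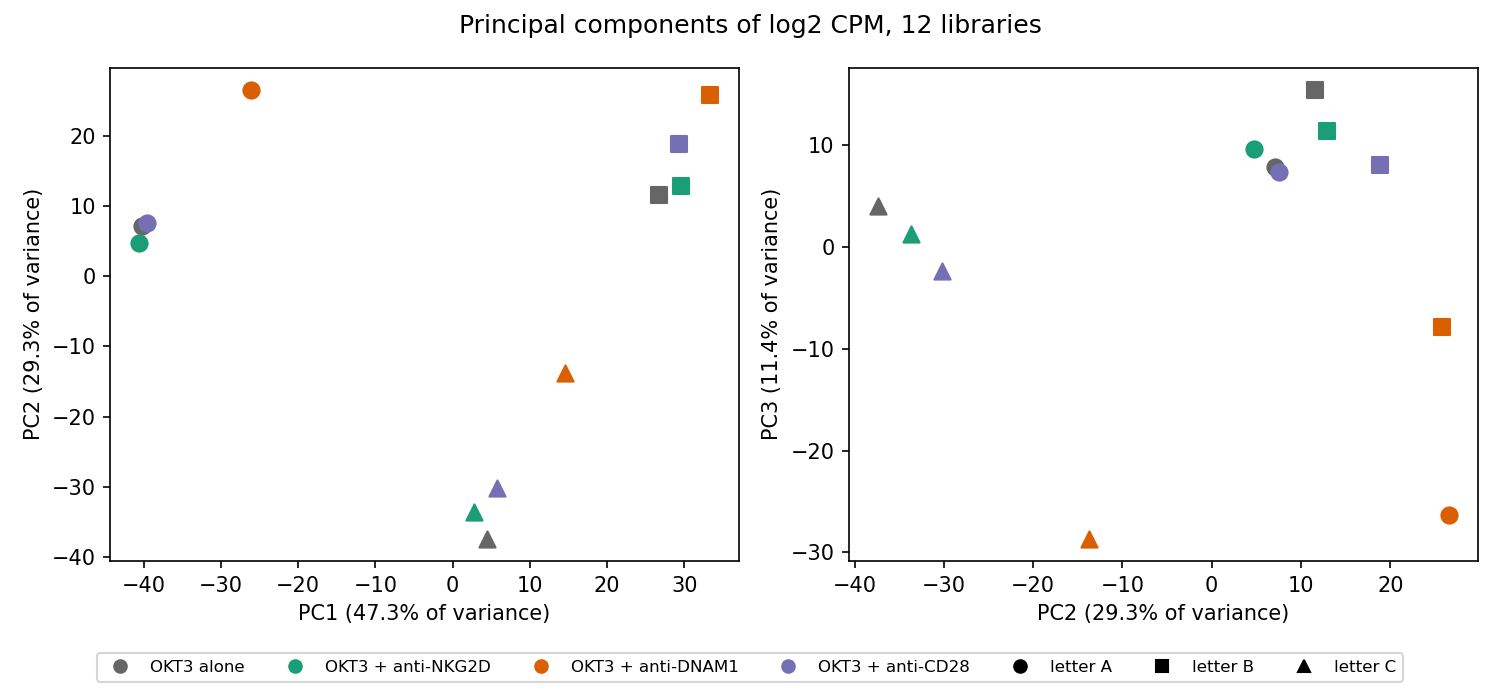
Principal components of log2 CPM of the 12 libraries, each point a library, with colour for the stimulus and the symbol for the letter. The left panel shows components 1 and 2 and the right panel components 2 and 3. The first 2 components (47.3% and 29.3% of the variance) separate the letters, and the next (11.4%) places the DNAM1 libraries at -28.7 to -7.88 and the 9 others at -2.31 to 15.5.

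Whether a DNAM1 signal changes transcription beyond the T cell receptor signal was asked by comparing DNAM1 with OKT3. Many cytokine and chemokine transcripts were higher with DNAM1. Of 39 tested cytokine and chemokine genes, 24 rose and 1 fell (29 changed when adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 1.54e-14, and adjusted p = 0.383 with an estimated correlation). IFNG, the main interferon of cytotoxic T cells, averaged 6647 ± 2311 CPM with DNAM1 and 3014 ± 1855 CPM with OKT3 (SD, n = 3), a log2 fold change of 1.36 ± 0.22 (SE, edgeR adjusted p = 0.00260). CSF2, which encodes the growth factor GM-CSF, averaged 1291 ± 401 and 540.0 ± 321 CPM (1.41 ± 0.17, edgeR adjusted p = 0.000613). The chemokine gene CCL1 rose by 1.55 ± 0.11 on the log2 scale and IL2, the T cell growth factor, by 0.96 ± 0.17 (edgeR adjusted p = 0.000159 and 0.00396). IL31, CSF1 and XCL1 also rose, by 1.72, 1.03 and 1.19, the last uncertain because XCL2 is a near-identical copy. TNF had a log2 fold change of 0.53 ± 0.19 and missed the threshold (edgeR adjusted p = 0.0670), which it passed without letter A (0.0418) or B (0.0136), with no filter and with all 12 libraries (0.0142), in a range of 3.25e-12 to 0.286 over its alternatives. Every gene named here as risen or fallen moved the same way in 3 of 3 letters.

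Receptors and killing machinery moved in parts. Among 28 costimulatory receptors and activation markers, 18 rose and 1 fell (21 adjusted over the list alone, median 0.44, camera adjusted p = 1.70e-10, and adjusted p = 0.383 with an estimated correlation). TNFRSF9, the costimulatory receptor 4-1BB, showed a log2 fold change of 1.77 ± 0.16 (459.6 ± 231 against 163 ± 144 CPM, edgeR adjusted p = 0.000265). CD109, TNFRSF18 (GITR) and IL2RA (the alpha chain of the IL-2 receptor) rose by 1.37, 1.29 and 0.75. Of 24 inhibitory receptor and exhaustion genes, 11 rose and 3 fell (16 adjusted over the list alone, camera adjusted p = 2.71e-05, and adjusted p = 0.383 with an estimated correlation). LAG3, an inhibitory receptor, rose by 1.05 ± 0.10, and CBLB, a ubiquitin ligase that restrains T cell signalling, by 0.48 ± 0.08. The 23 cytotoxic effector genes went both ways, 11 higher and 6 lower (20 adjusted over the list alone, camera adjusted p = 0.0451, and adjusted p = 0.672 with an estimated correlation). GZMB, the protease granzyme B, rose from 2110.0 ± 1019 to 4271 ± 1111 CPM (1.17 ± 0.14, edgeR adjusted p = 0.000664). SRGN and RAB27A of the granule pathway rose by 0.70 and 0.52, and the transcription factor gene ZNF683 (Hobit) fell, with a log2 fold change of -1.20 ± 0.08. NK receptors and adaptors split evenly, with 4 higher and 4 lower of 22 (8 adjusted over the list alone; camera adjusted p = 0.671). CD226, the gene of the engaged receptor, was higher with DNAM1 (0.45 ± 0.07, edgeR adjusted p = 0.00188), as was CRTAM (1.28). CD28 (0.16 ± 0.08, edgeR adjusted p = 0.170) and KLRK1 (-0.48 ± 0.18, 0.0826) did not pass the threshold. Without letter B both passed it (CD28 0.0294, range 0.0294 to 0.672 over its alternatives, and KLRK1 0.0235, range 0.0101 to 0.399), and KLRK1 also with no filter and with all 12 libraries (0.0438).

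Ribosome biogenesis had the largest share of called members among the lists. Of its 40 genes, 39 rose with DNAM1 and 0 fell (40 adjusted over the list alone, and 39 so adjusted without the block), with a median log2 fold change of 0.74 (camera adjusted p = 1.30e-55, and adjusted p = 0.383 with an estimated correlation, fry adjusted p = 0.0580 with the block and 0.0402 without it). WDR12, a pre-rRNA processing factor, averaged 84.5 ± 5.50 CPM with DNAM1 and 41.7 ± 7.97 CPM with OKT3 (1.07 ± 0.09, edgeR adjusted p = 0.000202). MRTO4, PES1 and UTP20 rose by 0.91, 0.74 and 0.85. MYC, a transcription factor that drives ribosome production, rose by 0.88 ± 0.14 to 641 ± 88.5 CPM (edgeR adjusted p = 0.00268). Amino acid transport and one-carbon metabolism had 13 higher and 3 lower genes of 24 (16 adjusted over the list alone, camera adjusted p = 1.76e-06, and adjusted p = 0.383 with an estimated correlation). SRM, MTHFD1L and SLC7A1 rose by 0.77, 0.91 and 0.85. In glycolysis 8 of 25 genes rose and 1 fell (13 adjusted over the list alone, camera adjusted p = 0.000965, and adjusted p = 0.383 with an estimated correlation). HK2, the hexokinase that starts the pathway, rose by 1.28 ± 0.10 and PFKP by 0.80. Cholesterol synthesis had 11 higher and 2 lower of 29 (16 adjusted over the list alone, camera adjusted p = 0.00518, and adjusted p = 0.383 with an estimated correlation), with STARD4 at 1.06 and HMGCS1 at 0.72.

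Targets of activating signals rose in part as well. The early response list had 16 higher and 0 lower of 32 genes (17 adjusted over the list alone, median 0.35, camera adjusted p = 1.76e-06, and adjusted p = 0.575 with an estimated correlation). DUSP4, a phosphatase of MAP kinases, rose by 1.02 ± 0.09 and BATF3 by 1.12. NF-kB targets had 15 higher and 2 lower of 34 (19 adjusted over the list alone, camera adjusted p = 8.29e-05, and adjusted p = 0.562 with an estimated correlation), including SDC4 (1.07) and the survival gene BCL2L1 (0.75). Calcium and NFAT targets had 14 and 1 of 24 (18 adjusted over the list alone, camera adjusted p = 3.17e-08, and adjusted p = 0.383 with an estimated correlation). IL-2 and STAT5 targets had 12 and 1 of 27 (14 adjusted over the list alone, camera adjusted p = 1.17e-07, and adjusted p = 0.383 with an estimated correlation). CDK6, a cell cycle kinase, rose by 1.02 and STAT5A by 0.78. The integrated stress response had 6 higher and 0 lower of 19 (8 adjusted over the list alone, camera adjusted p = 0.00507, and adjusted p = 0.562 with an estimated correlation). Heat shock had 8 and 1 of 17 (11 adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.527 with an estimated correlation). The chaperone genes HSPA5 and HSP90AB1 rose by 0.65 and 0.73.

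Many genes of resting and recirculating T cells were lower with DNAM1. Of 28 naive, memory and quiescence genes, 15 fell and 4 rose (24 adjusted over the list alone, median -0.24, camera adjusted p = 6.62e-05, and adjusted p = 0.383 with an estimated correlation). Of 20 PI3K-AKT-FOXO targets, 12 fell and 1 rose (15 adjusted over the list alone, median -0.31, camera adjusted p = 3.17e-08, and adjusted p = 0.383 with an estimated correlation). IL7R, the receptor of the survival cytokine IL-7, fell from 1139 ± 102 to 698 ± 49.2 CPM (-0.67 ± 0.07, edgeR adjusted p = 0.000306). KLF2, a transcription factor of quiescent and migrating T cells, and TSC22D3 (GILZ) fell as well, with log2 fold changes of -1.03 ± 0.10 and -1.23 ± 0.15 (edgeR adjusted p = 0.000333 and 0.000696). In the cell cycle list 17 genes fell and 2 rose of 41 (22 adjusted over the list alone, median -0.17, camera adjusted p = 0.00219, and adjusted p = 0.562 with an estimated correlation). E2F2 stood at -0.67 and CDK4 at 0.41. Interferon-stimulated genes had 5 higher and 9 lower of 36 (17 adjusted over the list alone; camera adjusted p = 0.294).

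Many of the largest single changes lay outside these programs. Among the 10 largest increases by the naming rule were ICAM5, an adhesion molecule (2.53 ± 0.27, 2.59 ± 1.08 against 0.442 ± 0.0534 CPM, edgeR adjusted p = 0.000396), the homeobox gene PRRX2 (2.33 ± 0.18), PTGIS, which encodes prostacyclin synthase (2.14 ± 0.14, 58.1 ± 32.8 against 14.4 ± 9.51 CPM), TNFRSF21 (1.96 ± 0.22) and SIPA1L2 (1.93 ± 0.15). Among the 10 largest decreases were CR1, a complement receptor (-2.09 ± 0.33, 0.386 ± 0.200 against 1.64 ± 0.294 CPM, edgeR adjusted p = 0.00217), MAP2K6, a kinase upstream of p38 (-1.78 ± 0.15), the ephrin receptor gene EPHA4 (-1.76 ± 0.19), ACKR3 (-1.41 ± 0.26) and VIPR1 (-1.38 ± 0.10). All were called with the block.

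Markers of cell types and of RNA quality were counted in the same fit. CD8 T cell identity genes had 2 higher and 5 lower of 17 (7 adjusted over the list alone; camera adjusted p = 0.350). NK cell markers had 3 and 2 of 8 (6 adjusted over the list alone; camera adjusted p = 0.348). CD4 and regulatory T cell markers had 2 and 0 of 11 (2 over the list alone, camera adjusted p = 0.352) and gamma delta T cell markers 0 and 2 of 8 (2 over the list alone, camera adjusted p = 0.171). CD40LG, an activation-induced ligand kept in the CD4 list, was among the risen ones (0.95 ± 0.17, edgeR adjusted p = 0.00368). The B cell, monocyte and red cell lists had fewer than 3 tested genes. CD79B of the first stood at 4.58 ± 2.15 CPM with DNAM1 and 8.16 ± 4.34 CPM with OKT3 (-0.75 ± 0.16, edgeR adjusted p = 0.00843), a call lost without letter A (0.0580, range 4.27e-06 to 0.0580 over its alternatives). IL3RA, the most abundant monocyte marker, stood at 14.2 and 15.9 CPM, and TUBB1, the most abundant of the red cell and platelet list, at 0.704 and 0.875 CPM. Replication-dependent histones had 0 higher and 2 lower of 42 (1 adjusted over the list alone, camera adjusted p = 0.0400, and adjusted p = 0.485 with an estimated correlation). No member of the small non-coding, nuclear retained or mitochondrially encoded lists passed (0 of 10, 5 and 15 tested by edgeR, and 0 adjusted over each list alone), at camera adjusted p = 0.980, 0.595 and 0.60.

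Over all 15846 tested genes, edgeR with the block called 4227 between DNAM1 and OKT3, 2184 higher and 2043 lower, of which 321 changed by a log2 value of at least 1 (213 higher, 108 lower). With no normalization factors the 4345 calls were 1838 higher and 2507 lower (42.3% higher, against 51.7%), so the balance of the directions depends on the scaling. The count was 2154 without letter A, 4497 without B and 2878 without C. Without the block edgeR called 0, with 1988 genes at an unadjusted p under 0.05 (792 expected) and a smallest adjusted p of 0.144, while DESeq2 called 689 and limma-voom 0. No list call held with an estimated correlation, in either fit, a form of the test with few degrees of freedom here.

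**Figure D2:**
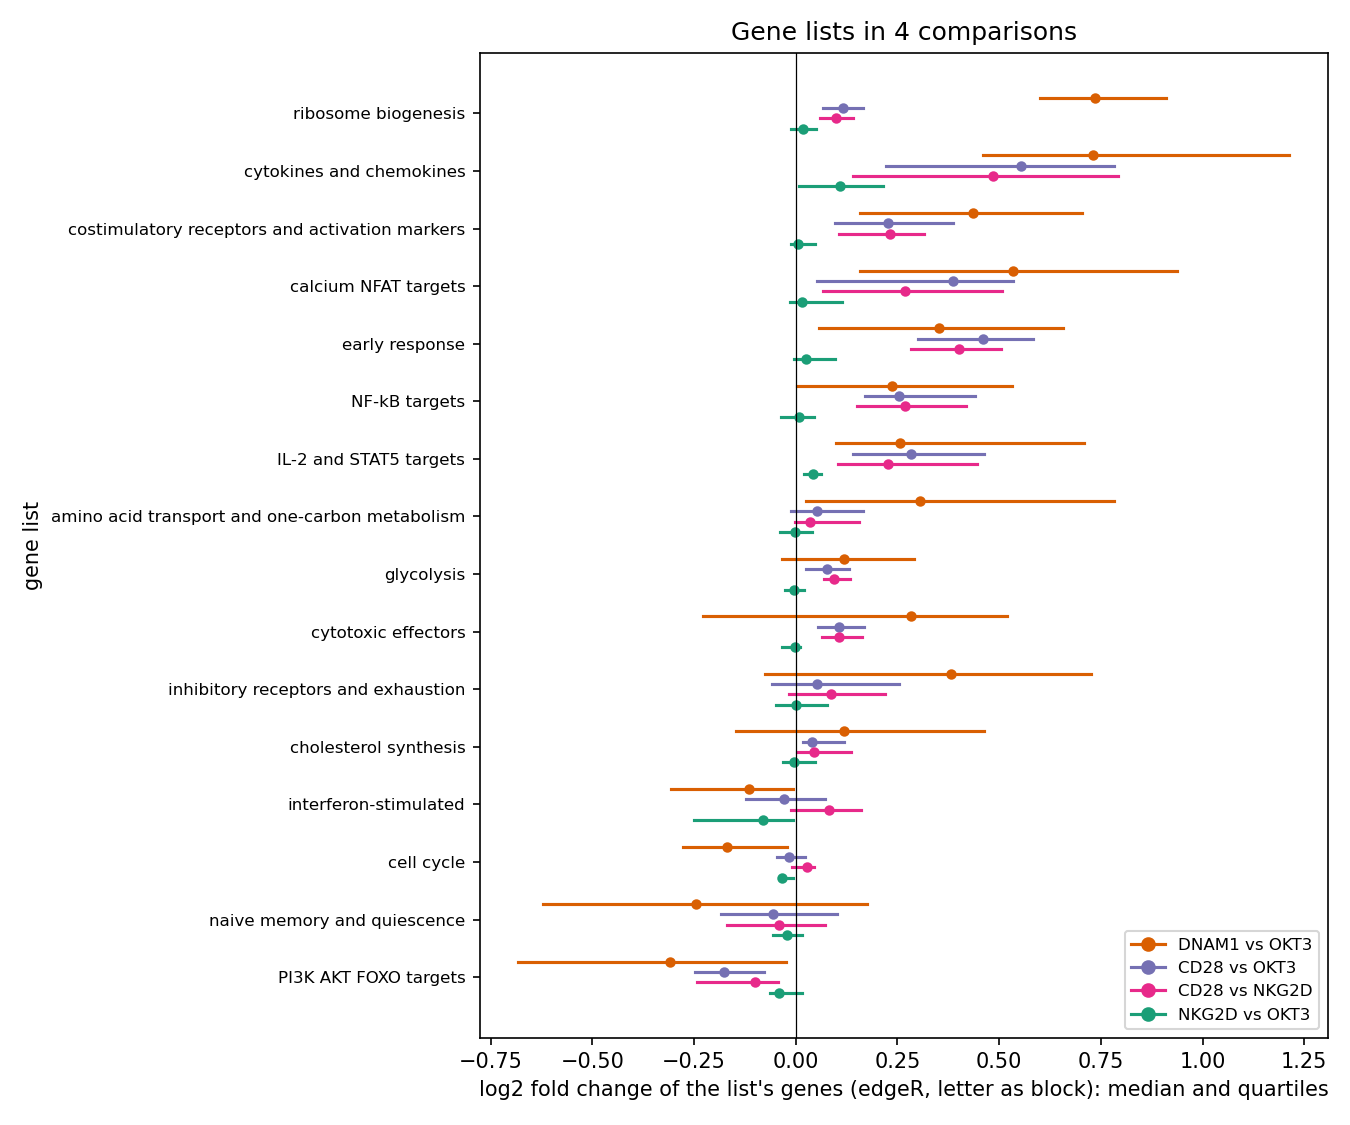
Median log2 fold change (points) and quartiles (bars) over the tested genes of 16 lists in 4 comparisons, from the fits with the block. Ribosome biogenesis has a median of 0.74 for DNAM1 over OKT3 and 0.10 for CD28 over NKG2D, and the early response list 0.35 and 0.40.

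CD28 and NKG2D, the 2 stimuli that share the polyA kit in the labels, were compared to see how the classical costimulus and an NK receptor differ. Many early response and cytokine genes were higher with CD28. Of 32 early response genes, 22 rose and 0 fell (30 adjusted over the list alone), at a median log2 fold change of 0.40 (camera adjusted p = 5.80e-79, and adjusted p = 0.123 with an estimated correlation). MYC averaged 534 ± 126 CPM with CD28 and 372 ± 71.6 CPM with NKG2D (SD, n = 3), a log2 fold change of 0.56 ± 0.06 (edgeR adjusted p = 6.19e-05). NR4A1, a nuclear receptor induced by receptor signalling, DUSP6 and JUNB rose by 0.52 ± 0.07, 0.50 ± 0.07 and 0.37 ± 0.06. Among 39 cytokines and chemokines, 17 rose and 0 fell (30 adjusted over the list alone, median 0.49, camera adjusted p = 7.25e-61, and adjusted p = 0.121 with an estimated correlation). IL2 averaged 129.9 ± 62.9 against 68.2 ± 46.1 CPM (1.20 ± 0.14, edgeR adjusted p = 0.000157). CXCL8, IL6, IL22, IL4 and IL21 rose by 1.41 ± 0.19, 1.21 ± 0.11, 1.10 ± 0.16, 0.90 ± 0.10 and 0.86 ± 0.10. TNF (0.70 ± 0.07, edgeR adjusted p = 4.84e-05), CSF2 (0.70 ± 0.06, 2.12e-06) and IFNG (0.54 ± 0.08, 0.00173) were higher too. Each of these genes moved the same way in 3 of 3 letters.

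Signalling targets followed the same direction. NF-kB targets had 13 higher and 0 lower of 34 (25 adjusted over the list alone, camera adjusted p = 6.68e-46, and adjusted p = 0.123 with an estimated correlation). NFKBIA, the inhibitor that NF-kB itself induces, rose by 0.34 ± 0.06 and BCL2L1 by 0.43. Calcium and NFAT targets had 12 and 0 of 24 (15 adjusted over the list alone, camera adjusted p = 6.04e-38, and adjusted p = 0.121 with an estimated correlation). IL-2 and STAT5 targets had 11 and 0 of 27 (20 adjusted over the list alone, camera adjusted p = 7.98e-29, and adjusted p = 0.121 with an estimated correlation; without the block the latter was 0.0387). Costimulatory receptors and activation markers had 8 and 0 of 28 (19 adjusted over the list alone, camera adjusted p = 5.78e-17, and adjusted p = 0.123 with an estimated correlation). CD69, an early activation marker (0.48 ± 0.09, edgeR adjusted p = 0.0154), and IL2RA (0.44 ± 0.06, 0.000306) were among them. The CD69 call was lost with no normalization factors (0.0650), the length correction (0.0540, log2 fold change 0.45) and DESeq2 (0.441, range 3.68e-13 to 0.441 over its alternatives). TNFRSF9 (0.38 ± 0.07, edgeR adjusted p = 0.00503) and GZMB (0.23 ± 0.05, 0.0373) rose by less, and both calls were lost without letter A (0.135, range 8.20e-07 to 0.612 over its alternatives, and 0.117, range 7.99e-06 to 0.724). The GZMB call was also lost with no normalization factors (0.108) and the length correction (0.138). The receptor genes CD226 (-0.04 ± 0.07, edgeR adjusted p = 0.922), CD28 (-0.13 ± 0.06, 0.575) and KLRK1 (-0.35 ± 0.13, 0.426) did not pass the threshold.

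Few members of the other lists passed in this comparison. The cytotoxic effector list had 1 of 23 higher, GZMB (4 adjusted over the list alone, camera adjusted p = 3.14e-06, and adjusted p = 0.284 with an estimated correlation). The inhibitory list had 3 of 24 (5 over the list alone, camera adjusted p = 0.000240, and adjusted p = 0.268 with an estimated correlation). The integrated stress response had 2 of 19 (6 over the list alone, camera adjusted p = 7.64e-09, and adjusted p = 0.284 with an estimated correlation), with PPP1R15A at 0.47 ± 0.06. For ribosome biogenesis edgeR called 0 of 40 genes (0 adjusted over the list alone) at a median of 0.10 (camera adjusted p = 1.24e-05, and adjusted p = 0.284 with an estimated correlation), and for NK receptors and adaptors 0 of 22 (camera adjusted p = 0.741). Mitochondrially encoded genes had 0 of 15 called, and 9 adjusted over the list alone, at a median of 0.14 (camera adjusted p = 1.24e-05, and adjusted p = 0.355 with an estimated correlation). The mitochondrial share of counts was 5.15% ± 1.06 with CD28 and 4.85% ± 0.764 with NKG2D (SD, n = 3). Histones had 0 of 41 at a median of -0.25 (camera adjusted p = 0.00175, and adjusted p = 0.284 with an estimated correlation). Among cell type lists, NK cell markers had 1 of 8 higher (2 over the list alone, camera adjusted p = 0.00486, and adjusted p = 0.284 with an estimated correlation) and CD4 and regulatory T cell markers 0 of 11 (1 over the list alone, camera adjusted p = 0.0127, and adjusted p = 0.284 with an estimated correlation). Camera with the block also called glycolysis, amino acid transport, cholesterol synthesis and interferon-stimulated genes higher and PI3K-AKT-FOXO targets lower, with at most 1 gene of each called by edgeR, and none of the 5 held with an estimated correlation (adjusted p = 0.284 to 0.357). RN7SL1, a small non-coding RNA, rose by 1.32 ± 0.24 (edgeR adjusted p = 0.00923), from 4.09 ± 1.35 to 10.4 ± 5.63 CPM. The CPM values rose in letters A (5.12 to 15.8) and C (2.56 to 10.8) and were level in B, and the call was lost in DESeq2 with the block (0.491) and with the length correction (0.0517, log2 fold change 1.27, range 7.71e-18 to 0.491 over its alternatives).

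Of the 11 genes called lower with CD28, 7 had over 10 kb of exons. ISM1 (-0.92 ± 0.19, edgeR adjusted p = 0.0195), AHNAK, a giant scaffold protein gene (-0.42 ± 0.08, 1490.0 ± 202 against 2055 ± 235 CPM, 0.0106), and SYNE2, which encodes a nuclear envelope protein (-0.40 ± 0.07, 0.00649), were among the 11. The 11 lower genes had a median exon length of 17053 nt, against 3198 nt for the higher and 4290 nt for all tested genes. With a length correction edgeR called 3 genes lower, against 11 before, and 89 higher, against 111. AHNAK and SYNE2 were no longer called then (edgeR adjusted p = 0.0722, range 8.57e-20 to 0.459 over its alternatives, and 0.0720, range 2.63e-09 to 0.431), while their log2 fold changes kept their sign, at -0.32 and -0.26. DESeq2 with the block did not call AHNAK either (0.459). The call of ISM1 was lost in limma-voom with the block (adjusted p = 0.0925, range 4.00e-07 to 0.185).

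Of 15884 tested genes, edgeR with the block called 122, 111 higher and 11 lower with CD28, 7 of them by a log2 value of at least 1. With no normalization factors the 113 calls were 84 higher and 29 lower (74.3% higher, against 91.0%). Without the block edgeR called 0, with 79 genes at an unadjusted p under 0.05 (794 expected), and DESeq2 and limma-voom also called 0. The count was 93 without letter A (76 higher, 17 lower), 330 without B (194 and 136) and 270 without C (179 and 91), so the balance of the directions depends on single letters. When all 12 libraries shared 1 fit with the block it was 1, IL4 (edgeR adjusted p = 0.0373, range 1.05e-12 to 0.0373 over its alternatives), so that every other gene named here lost its call in that fit. DESeq2 with the block did not call IL2 (adjusted p = 0.0621, range 2.55e-53 to 0.10) or IFNG (0.249, range 1.41e-45 to 0.537).

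**Figure D3:**
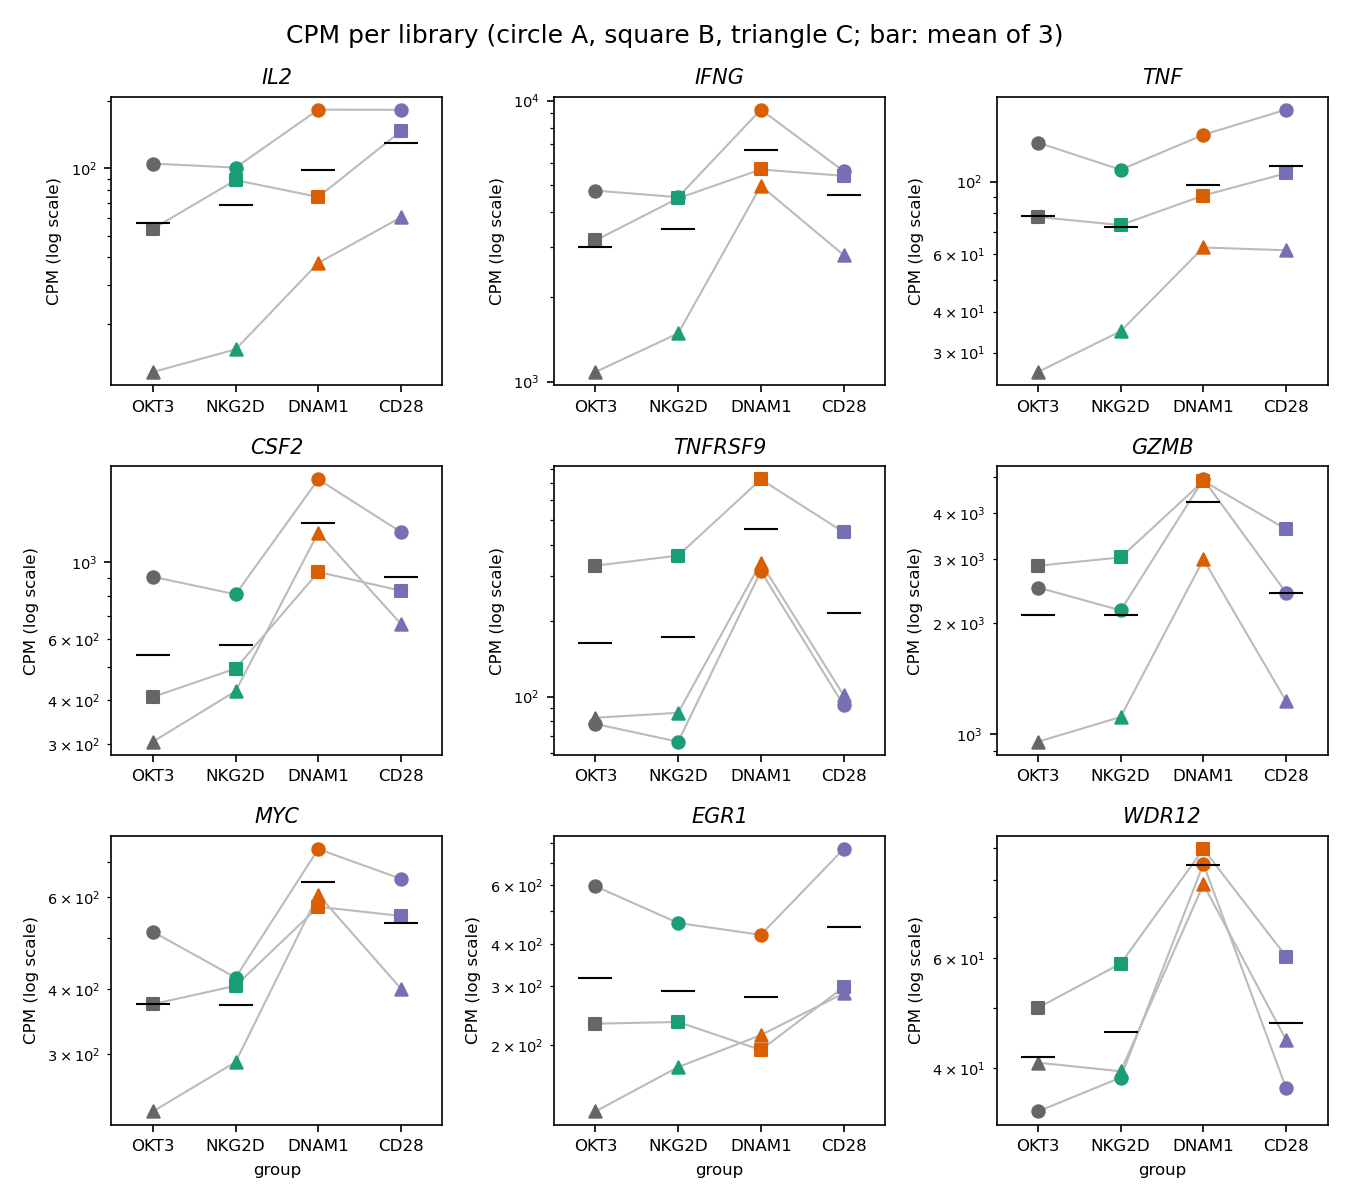
CPM of 9 genes in each of the 12 libraries on a log axis, grouped by stimulus, with symbols for the letters, lines that join each letter across the stimuli and bars for group means. IFNG averages 6647 ± 2311 CPM with DNAM1 and 3014 ± 1855 CPM with OKT3 (SD, n = 3), and IL2 129.9 ± 62.9 CPM with CD28.

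CD28 was also compared with OKT3 alone, the classical test of costimulation. Here the labels give the groups different kits, so that kit and stimulus cannot be told apart by design. Histones and small non-coding RNA, which a polyA kit should deplete, took a median of 0.00950% of counts in libraries labelled rRNA-depleted and 0.00896% in those labelled polyA, a ratio of 1.06. The histone list was lower with CD28 than with OKT3, the direction of a polyA kit, at a median of -0.37 with 0 of 41 genes called (camera adjusted p = 2.00e-08, and adjusted p = 0.182 with an estimated correlation, fry adjusted p = 0.0187). Within a kit its median was -0.27 for DNAM1 over OKT3 and -0.25 for CD28 over NKG2D. Across the kits it was -0.11 for NKG2D over OKT3, lower with the polyA label, and -0.11 for DNAM1 over NKG2D, lower with the rRNA-depleted label. The small non-coding share went the other way, with 0.00193% of counts with CD28 and 0.00134% with OKT3. Most of that rise came from RN7SL1 (10.4 and 4.78 CPM), and with NKG2D the share was 0.00126%, the direction of a polyA kit. Of 32 early response genes 25 rose with CD28 (29 adjusted over the list alone, median 0.46, camera adjusted p = 1.34e-60, and adjusted p = 0.182 with an estimated correlation). Of 39 cytokines and chemokines, 20 rose (26 adjusted over the list alone, median 0.55, camera adjusted p = 2.24e-57, and adjusted p = 0.182 with an estimated correlation). IL2 averaged 129.9 ± 62.9 CPM with CD28 and 56.9 ± 46.4 CPM with OKT3 (SD, n = 3), a log2 fold change of 1.5 ± 0.15 (edgeR adjusted p = 8.51e-06). IL22, CXCL8, IL21 and CSF2 rose by 1.49 ± 0.20, 1.35 ± 0.19, 1.07 ± 0.11 and 0.90 ± 0.09, each higher in 3 of 3 letters and still called when any 1 letter was left out. IL21 lost its call in the fit of all 12 libraries (0.0846, range 9.90e-38 to 0.0846 over its alternatives). IL4 (0.86 ± 0.11), IFNG (0.84 ± 0.12), TNF (0.69 ± 0.11), FOSB (0.89 ± 0.14) and TNFRSF9 (0.37 ± 0.06) were called with edgeR adjusted p = 0.000255, 0.000383, 0.000783, 0.000945 and 0.00157. Those 5 calls were lost without letter B, at 0.0554, 0.0999, 0.0616, 0.0793 and 0.174, where the highest values over their alternatives were 0.0554, 0.160, 0.153, 0.174 and 0.519. DESeq2 with the block did not call IFNG, TNF and FOSB (adjusted p = 0.124, 0.153 and 0.174).

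Among signalling targets, NF-kB targets (18 of 34 higher, 25 adjusted over the list alone, camera adjusted p = 1.09e-39, and adjusted p = 0.182 with an estimated correlation) and IL-2 and STAT5 targets (15 of 27, 21 over the list alone, camera adjusted p = 1.11e-25, and adjusted p = 0.182 with an estimated correlation) rose with CD28. So did calcium and NFAT targets (13 of 24, 15 over the list alone, camera adjusted p = 1.60e-29, and adjusted p = 0.182 with an estimated correlation) and costimulatory receptors (12 of 28, 21 over the list alone, camera adjusted p = 1.53e-16, and adjusted p = 0.182 with an estimated correlation), and 0 members of these 4 lists were lower. Mitochondrially encoded genes rose in 8 of 15 (15 adjusted over the list alone, camera adjusted p = 1.84e-12, and adjusted p = 0.209 with an estimated correlation), with a share of counts of 5.15% ± 1.06 with CD28 and 4.65% ± 1.11 with OKT3 (SD, n = 3). NK cell markers rose in 2 of 8 (4 over the list alone, camera adjusted p = 0.00839, and adjusted p = 0.213 with an estimated correlation) and CD4 and regulatory T cell markers in 1 of 11 (1, camera adjusted p = 0.0420, and adjusted p = 0.485 with an estimated correlation). Ribosome biogenesis had 1 of 40 higher (7 adjusted over the list alone, median 0.12, camera adjusted p = 4.14e-08, and adjusted p = 0.485 with an estimated correlation). GZMB had a log2 fold change of 0.26 ± 0.07 (edgeR adjusted p = 0.0399), a call lost without letter B (0.575) or C (0.333, range 7.93e-11 to 0.613 over its alternatives). It was also lost with no normalization factors (0.158), all 12 libraries (0.613), the length correction (0.144), the GC correction (0.0536) and thinning (0.0674). CD226 (0.01 ± 0.06, edgeR adjusted p = 0.983), CD28 (-0.13 ± 0.06, 0.348) and KLRK1 (-0.35 ± 0.13, 0.258) did not pass. Over 15824 genes edgeR with the block called 301, 215 higher and 86 lower, 11 by a log2 value of at least 1. It called 748 without letter A (509 higher, 239 lower), 27 without B (23 and 4) and 199 without C (100 and 99), 168 with no normalization factors (81 higher and 87 lower, 48.2% higher against 71.4%), and 19 with all 12 libraries in 1 fit. Without the block edgeR called 0 (108 at an unadjusted p under 0.05, 791 expected), as did DESeq2 and limma-voom.

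NKG2D added to OKT3 gave no gene past the threshold, in a comparison that also crosses the kits of the labels. IL2 had a log2 fold change of 0.33 ± 0.10, IFNG of 0.29 ± 0.08, TNF of 0.00 ± 0.09, GZMB of 0.03 ± 0.06 and TNFRSF9 of -0.01 ± 0.07 (SE of the fit), all with an edgeR adjusted p of 1.00. The differences within a letter had an SD of 0.39 for IL2, 0.32 for IFNG and 0.36 for TNF (n = 3). Without letter A, and separately in the fit with no filter, IL2 and IFNG passed (without A, edgeR adjusted p = 0.0415, range 0.0239 to 1.00 over its alternatives, and 0.00113, range 3.29e-10 to 1.00). CD226, CD28 and KLRK1 stood at 0.05 ± 0.06, -0.01 ± 0.05 and 0.00 ± 0.12. Among lists, camera with the block called cytokines and chemokines higher (median 0.11, 0 of 38 genes called and 2 adjusted over the list alone, camera adjusted p = 1.17e-05, and adjusted p = 0.914 with an estimated correlation) and mitochondrially encoded genes higher (median 0.09, camera adjusted p = 0.000579, and adjusted p = 0.914 with an estimated correlation). It called interferon-stimulated genes (median -0.08, camera adjusted p = 1.25e-05, and adjusted p = 0.914 with an estimated correlation) and histones (median -0.11, camera adjusted p = 0.00121, and adjusted p = 0.914 with an estimated correlation) lower. For calcium and NFAT targets the median was 0.01 (camera adjusted p = 0.0243, and adjusted p = 0.914 with an estimated correlation). Of 15911 genes edgeR called 0 with the block (311 at an unadjusted p under 0.05, 796 expected) and 0 without it (38), and DESeq2 and limma-voom called 0. Leaving out letter A, B or C gave 9, 2 and 3 calls with the block.

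The effects of DNAM1 over OKT3 and of CD28 over NKG2D share no library and were set against each other across 15400 genes, which are not independent replicates. Their log2 fold changes correlated at a Pearson value of 0.183 (Spearman 0.233) without the block, with 59.5% of genes on the same side of 0. Over the 8373 genes of at least 10 CPM the Pearson value was 0.369, with 62.1% on the same side. Of the 111 genes that rose with CD28, 67 also rose with DNAM1, where independent lists would share 15.7, and 0 fell (14.7 for independent lists). Of the 11 that fell with CD28, 7 also fell with DNAM1 (1.46) and 1 rose (1.55). CSF2, IL2 and MYC rose in both, with CSF2 at 1.41 and 0.70, IL2 at 0.96 and 1.20 and MYC at 0.88 and 0.56. Ribosome biogenesis had 39 of 40 genes called in one comparison and 0 in the other. The difference between the 2 effects was not tested.

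**Figure D4:**
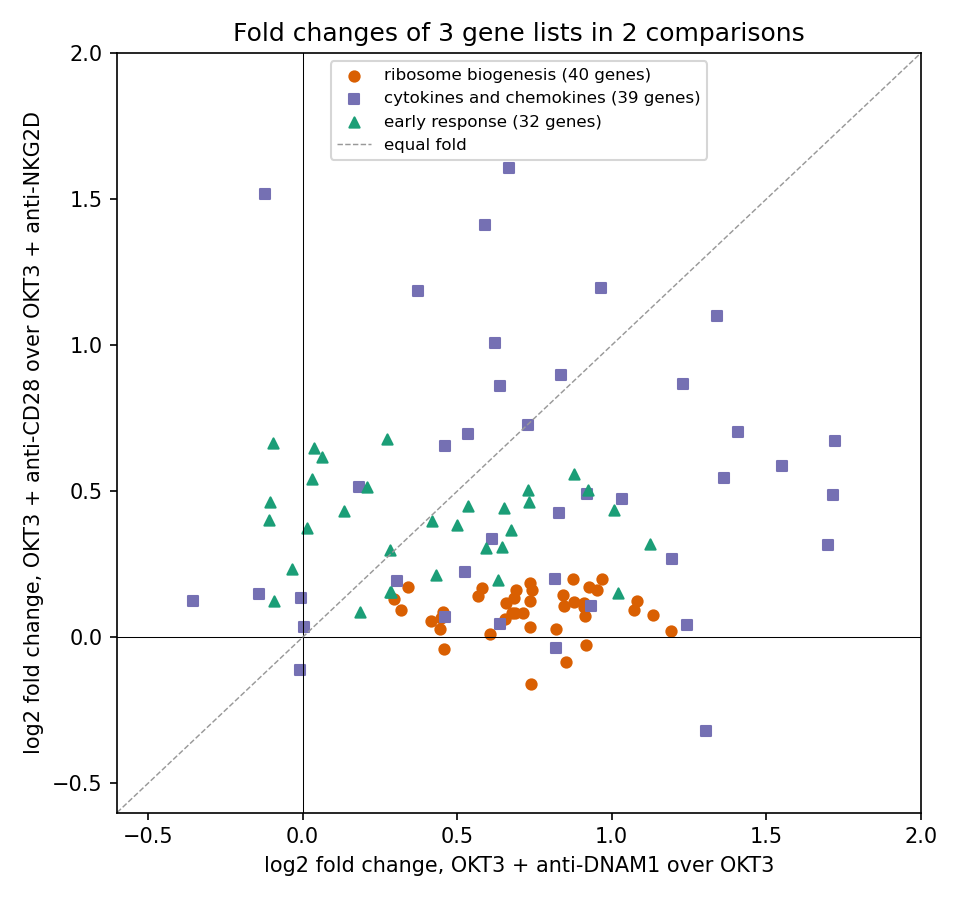
Log2 fold changes of DNAM1 over OKT3 (horizontal) and CD28 over NKG2D (vertical) from the fits with the block, each point a gene of the ribosome biogenesis (40 genes), cytokine (39) or early response list (32). Ribosome biogenesis genes spread along the horizontal axis (medians 0.74 and 0.10), and early response genes have medians of 0.35 and 0.40.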

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

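All fits that add a choice to the block were chosen after seeing the data, except leaving out letters and DESeq2. Adding the letter as a replicate block took the genes called by edgeR from 0 to 4227 (DNAM1 over OKT3), 122 (CD28 over NKG2D), 301 (CD28 over OKT3), 2368 (DNAM1 over CD28) and 2467 (DNAM1 over NKG2D), and left NKG2D over OKT3 at 0. In the simulated data, which carried letter effects by construction, edgeR without the block recovered 0% of genes changed by 2-fold, and DESeq2 without it 58% to 65%. For the other changes of a count the cause was not tested, except that a fold minimum leaves fewer genes by construction. No named gene called with the block turned its direction. Among named genes that were not called, 61 values of 30 genes and comparisons changed sign under an alternative, such as TNF for NKG2D over OKT3, and 0 of these were called then. Over the alternatives of the named genes with the block, called or not, 1553 values stayed on their side of the threshold for DNAM1 over OKT3, 14 lost a call and 21 gained one, and for CD28 over NKG2D 1385, 106 and 57. For CD28 over OKT3 161 stayed on their side and 25 lost a call. For NKG2D over OKT3, where no named gene was called, 92 stayed uncalled and 4 gained a call. The numbers were 348, 24 and 0 for DNAM1 over CD28 and 344, 5 and 11 for DNAM1 over NKG2D.

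Without the block, dropping the expression filter gave 4 calls for DNAM1 over OKT3 and 10 for DNAM1 over NKG2D, DESeq2 gave 689, 102 and 345 for DNAM1 over OKT3, CD28 and NKG2D, and all 12 libraries in 1 fit gave 2 for DNAM1 over OKT3 and 2 for DNAM1 over NKG2D. Leaving out any 1 library left 0 calls by edgeR in each of the 6 comparisons, and RLE, limma-voom and a log2 value of at least 1 left 0 as well.

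With the block, leaving out a letter gave 2154 to 4497 calls for DNAM1 over OKT3 (letters A and B), 93 to 330 for CD28 over NKG2D (A and B, 270 for C, 81.7% to 58.8% higher against 91.0%) and 2 to 9 for NKG2D over OKT3 (B and A, 3 for C). It gave 27 to 748 for CD28 over OKT3 (B and A, 199 for C), 692 to 3407 for DNAM1 over CD28 (A and B, 978 for C) and 522 to 4356 for DNAM1 over NKG2D (A and B, 1550 for C). With all 12 libraries in 1 fit the counts were 1 for CD28 over NKG2D, 19 for CD28 over OKT3 and 4068 for DNAM1 over NKG2D. The latter were 2029 higher and 2039 lower, and for DNAM1 over CD28 that fit turned the majority as well, with 1658 higher and 1749 lower. With no filter the counts were 283 for CD28 over NKG2D (199 higher, 84 lower), 14 for NKG2D over OKT3 and 512 for CD28 over OKT3. The GC correction gave 237 for CD28 over NKG2D (183 higher, 54 lower), and no normalization factors gave 168 for CD28 over OKT3. With no normalization factors the majority of the calls turned from higher to lower in 3 comparisons, from 51.7% to 42.3% higher for DNAM1 over OKT3 (1838 higher, 2507 lower), from 71.4% to 48.2% for CD28 over OKT3 (81 and 87) and from 60.5% to 44.4% for DNAM1 over NKG2D (1225 and 1533). A log2 value of at least 1 left 321, 7, 11, 188 and 241 calls for DNAM1 over OKT3, CD28 over NKG2D, CD28 over OKT3, DNAM1 over CD28 and DNAM1 over NKG2D. RLE, limma-voom, DESeq2, thinning and the length correction kept every count with the block within 1.5 times, with 3635 to 4290 calls for DNAM1 over OKT3. Similar counts did not always hold the same genes. Of the 301 calls for CD28 over OKT3, DESeq2 shared 186 and the length correction 196. DESeq2 shared 3585 of the 4227 for DNAM1 over OKT3 and 109 of the 122 for CD28 over NKG2D. The lowest adjusted p of many ranges given for single genes comes from the fit with no filter.

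Camera without the block called 16 of 27 lists for DNAM1 over OKT3, 13 of 29 for CD28 over NKG2D, 1 of 28 for NKG2D over OKT3, 12 of 29 for CD28 over OKT3, 6 of 29 for DNAM1 over CD28 and 15 of 29 for DNAM1 over NKG2D. With an estimated correlation, and so few degrees of freedom, these became 0, 1, 0, 0, 0 and 0, and with fry 2, 0, 0, 0, 0 and 0. With the block camera called 18, 19, 5, 19, 12 and 18, with the block and an estimated correlation 0 in all 6, and with the block and fry 0, 0, 0, 1, 0 and 2. Leaving out 1 library gave 12 to 19, 6 to 18, 2 to 13, 5 to 16, 4 to 14 and 12 to 21 lists. The lowest count for CD28 over NKG2D, 6, was without CD28 replicate B. The correlation between the effects of DNAM1 over OKT3 and CD28 over NKG2D was 0.183 over all genes, 0.177 with the block and 0.369 over genes of at least 10 CPM.

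Depth differed little between libraries, from 37377574 to 47268532 counts, and thinning to the lowest total left 4207 calls for DNAM1 over OKT3. Thinning moved no count with the block by over 1.5 times, whereas leaving out single letters moved counts with CD28 and with DNAM1 further. For NKG2D over OKT3 the simulated data recovered 81% of 1.5-fold changes with the block, while the data gave 0 calls, and 14 with no filter. The simulated changes were equal in all 3 letters and lay in well-counted genes. In the data IFNG differed by letter (-0.08 in A, 0.49 in B and 0.47 in C). The 81% therefore does not give the power of this comparison.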

Other observations

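Chosen after seeing the data were the direct comparisons of DNAM1 with CD28 and with NKG2D, the genes named from them outside the rule, the fits with the block that thin the counts or correct for exon length or GC content, and the tests of the kits and of the cytokine list with NKG2D.

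DNAM1 and CD28 differed in which activation genes they went with. Over 15812 genes edgeR with the block called 2368 between DNAM1 and CD28, 1264 higher and 1104 lower with DNAM1 (1658 and 1749 with all 12 libraries in 1 fit). It called 0 without the block, where 1274 genes had an unadjusted p under 0.05, DESeq2 called 102 and limma-voom 0. Ribosome biogenesis was higher with DNAM1 in 37 of 40 genes (39 adjusted over the list alone, median 0.64, camera adjusted p = 3.51e-46, and adjusted p = 0.676 with an estimated correlation), with WDR12 at 0.85 ± 0.10 (edgeR adjusted p = 0.000889). TNFRSF9 (1.39 ± 0.17, edgeR adjusted p = 0.000989), GZMB (0.91 ± 0.13, 0.00185), LAG3 (0.81) and IL3, a growth factor of myeloid cells (1.04 ± 0.11, 967 ± 423 against 472 ± 199 CPM), were higher with DNAM1 in 3 of 3 letters. The early response list went both ways, with 5 genes higher and 9 lower with DNAM1 of 32 (18 adjusted over the list alone, camera adjusted p = 0.648). The immediate early genes FOS (-0.65 ± 0.08, 81.5 ± 47 with DNAM1 against 132 ± 87.0 CPM with CD28, edgeR adjusted p = 0.000973), FOSB (-0.62 ± 0.09) and EGR1 (-0.64 ± 0.09) and the activation marker CD69 (-0.48 ± 0.07) were lower with DNAM1. IL2 was also lower with DNAM1 (-0.56 ± 0.14, edgeR adjusted p = 0.0253), a call that DESeq2 with the block (0.202) and the fit of all 12 libraries (0.0920, range 6.03e-09 to 0.202 over its alternatives) did not give.

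Against NKG2D, DNAM1 had 2467 called genes of 15969 with the block, 1492 higher and 975 lower, and 0 without it (1579 at an unadjusted p under 0.05, 345 by DESeq2, 0 by limma-voom). With no normalization factors the calls with the block were 1225 higher and 1533 lower, and with all 12 libraries in 1 fit 2029 and 2039. TNFRSF9 (1.80 ± 0.19), IL3 (1.38 ± 0.10), CSF2 (1.24 ± 0.11), GZMB (1.16 ± 0.12) and IFNG (1.10 ± 0.19, edgeR adjusted p = 0.00253) were higher with DNAM1, and EGR1 (0.03 ± 0.11, 0.881) and FOS (-0.01 ± 0.12, 0.971) did not pass. Ribosome biogenesis was higher in 39 of 40 genes (39 adjusted over the list alone, camera adjusted p = 2.91e-50, and adjusted p = 0.314 with an estimated correlation). Both comparisons cross the kits of the labels. Without letter A, B or C the counts were 692, 3407 and 978 against CD28 and 522, 4356 and 1550 against NKG2D, and camera with the block called NK cell markers higher than with NKG2D (camera adjusted p = 0.0436, and adjusted p = 0.436 with an estimated correlation) and mitochondrially encoded genes lower than with CD28 (camera adjusted p = 0.0421, and adjusted p = 0.751 with an estimated correlation). The mitochondrially encoded share of counts averaged 4.66% ± 1.20 with DNAM1, 4.85% ± 0.764 with NKG2D and 5.15% ± 1.06 with CD28 (SD, n = 3).

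The breadth of the change with DNAM1 was set against technical trends. Of its 4227 calls against OKT3, 96.3% were kept with the same sign when all libraries were thinned to the lowest total, 96.6% with a correction for exon length and 96.0% with one for GC content. The OKT3 and DNAM1 libraries held 41485253 to 46627085 counts, so thinning changed little and is a weak test of library size. Fold changes hardly followed exon length (Spearman -0.014) and followed GC content weakly (-0.115), so the corrections had little to remove. The values argue against length and GC content as the whole source. A response to DNAM1 engagement remains a hypothesis, and handling or timing that differed between the DNAM1 libraries and the rest was not testable with the labels. Among the 4 splits of the 6 libraries that part all 3 pairs, the real one gave 4227 calls and the highest other 0, and 4 splits, like the 10 of the fit without the block, are too few for a share under 0.05.

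Many genes lower with CD28 were long, which may reflect a length trend between libraries. Of the 86 genes lower than with OKT3, 56 had over 10 kb of exons (median exon length 13096 nt, against 4298 nt for all tested), and 41.9% stayed called after the length correction, and of the 215 higher ones 74.4%. The median fold of the lower genes moved from -0.30 (SD 0.23) to -0.25 (SD 0.25), and how near the threshold the lost calls lay was not tested. A length trend is a candidate cause of part of the lower calls, though most of their median fold remained. The values argue against it as the whole source of the higher ones. Whether such a trend comes from RNA integrity or from the cells stays open.

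The labels describe 2 kits, yet the ratio of the median histone and small non-coding share between them was 1.06, which argues against the kits having left the difference that rRNA depletion and polyA selection should leave. OKT3 and NKG2D libraries sharing a letter, labelled with different kits, were the most alike of all pairs (chi-square per gene 9.19, 10.9 and 10.4). With the block edgeR called 0 of 15911 genes between these groups, and 4227 between DNAM1 and OKT3 within a kit. These values argue against a large kit difference between the OKT3 and NKG2D libraries. Histones were lower with CD28 than with OKT3 (median log2 fold change -0.37), the direction of a polyA kit, but also lower within a kit (-0.27 for DNAM1 over OKT3 and -0.25 for CD28 over NKG2D). Against a trace of the kits, histones were lower with DNAM1 than with NKG2D (-0.11). The small non-coding share was higher with CD28 (0.00193%) than with OKT3 (0.00134%), mostly through its member RN7SL1 (10.4 and 4.78 CPM). The small non-coding list had a median log2 fold change of -0.105 for CD28 over OKT3 (camera adjusted p = 0.631). Share and list median of this class thus went opposite ways for CD28, which does not decide, and a smaller trace stays open. Whether the labels or the values are at fault was not tested. A response of the cytokine list to NKG2D is a further hypothesis: the median within-letter difference from OKT3 was above 0 in 2 of 3 letters (-0.11 in A, 0.14 in B, 0.27 in C), which does not decide.

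Splits of the libraries are too few for a share under 0.05 in the other comparisons too. With the block, the 4 splits that part all pairs gave 122 calls for the real one and at most 0 for another for CD28 over NKG2D, 301 and 0 for CD28 over OKT3, 2368 and 0 for DNAM1 over CD28, 2467 and 0 for DNAM1 over NKG2D, and 0 and 5 for NKG2D over OKT3. In the fit without the block the real split gave 0 calls in all 6 comparisons, and the highest of the other 9 gave 0 or 1.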
